A study of Caenorhabditis elegans with 17 samples.

How the data were processed

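The samples were 17 droplet libraries (10x Genomics) of dissociated C. elegans, mostly L4 larvae, sorted by flow cytometry for fluorescent reporters that mark all neurons or subsets of them. The labels gave the share of L4 as 68% (unc-47 replicate 1) to 98% (unc-53). They gave none for the nlp-13 and ceh-2 library and for the mixture with ceh-28. Per the labels, 11 libraries used chemistry version 2 and 6 used version 3, and worms were treated with SDS-DTT for 2 to 4 minutes before dissociation. Libraries were grouped by the marker of the sort, which gave 14 groups, of which the pan-neuronal, unc-47 and cho-1 groups had 2 libraries each and the others 1.

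The deposited matrix holds counts, that is, whole numbers of unique molecular identifiers (UMIs) per gene and cell, which the authors neither scaled nor log-transformed. Cells were named with a prefix, from which each cell was assigned to its library. Other deposited columns hold names: cell names, WormBase gene identifiers, and the authors' annotation of each cell with a tissue and a cell type, whose method was not stated. Per the submitters' processing notes, Cell Ranger 3.1.0 and the genome WBcel235 were used. The deposited gene models are WormBase WS273, per the file header, with 1012 records whose source field names an extension of 3' ends. Which droplets and genes were kept, how doublets were treated, and whether background RNA was subtracted, was not stated, and no doublets were removed here. Gene symbols were taken from Ensembl release 115 by WormBase identifier, which named 20945 of the 22469 genes in the matrix. The other 1524 genes held 1.92% of all UMIs and stayed in the tests under their identifiers.

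Counts were summed per library and cell class, with cell classes taken from the authors' annotation. The 6 comparisons set neurons against non-neuronal cells, ciliated sensory neurons against other neurons, pharyngeal against other neurons, cholinergic against GABAergic ventral cord motor neurons, ASER against ASEL, and AWC_ON against AWC_OFF. A library entered the first 4 comparisons with at least 30 cells in each arm, and the last 2 with at least 10. Both arms came from the same library, so the library was a block in the model. Genes were kept with filterByExpr and scaled by TMM, and tested two-sided with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. CPM, counts scaled to a sum of 1e6, were computed per library and arm from all UMIs of the arm, and means and SDs are over libraries.

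For a gene with no UMI in an arm, the bound is the other arm's mean CPM over the CPM that 3 counts over the whole arm would give. For a named gene with 1 to 3 UMIs in an arm, the ratio of the arms' summed counts is given with an exact 95% binomial interval. Intervals and floors cover counting error only. Shares of cells carry Wilson 95% intervals.

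The gene lists, the target types of each sort, the comparisons with their tests, and all alternatives but one were fixed before the data were examined. Tests of explanations came later, and the closing section names those chosen after the result was seen. The 25 lists were tested with camera (edgeR method, preset correlation 0.01, two-sided, adjusted over the lists of a comparison with at least 3 tested genes) and again with an estimated correlation. Lists of body wall muscle, pharyngeal muscle and gland, intestine, cuticle collagen, germline, glia and coelomocyte genes served as markers of other cells. Named genes were, per comparison, the 10 with the largest log2 fold change in each direction among called genes with at least 50 CPM in the higher arm and the same direction in every library, or in at least 90% of them where there were more than 5. To these came the 2 members with the smallest p in the direction of each list that camera called, and a fixed set of marker genes whatever their values. Named marker genes that the filter on low counts removed have their values from the fit without that filter.

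Specificity over neuron types was measured with the tau index, which is 0 for even expression and 1 for expression in a single type, on log2(CPM + 1). Profiles were means over libraries with at least 10 cells of a type, and genes with at least 5 CPM in the highest type were scored. The median of each list was set against 10000 random lists of the same size and similar mean expression. For genes carried on transgenes, each library had 1 value, the mean over neuron types of log2(CPM + 1) minus the mean of that type over libraries. Carriers and other libraries were compared by a two-sided exact permutation test, adjusted over the 6 genes. These steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6. Figures were drawn with matplotlib 3.10.9.

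The alternatives were DESeq2's size factors (RLE) within edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, no library block, a higher minimum of cells (100 or 20), each chemistry alone, only cells with at least 500 UMIs, at most 20 cells per library and type, and leaving out each library in turn. For specificity and transgene genes they were a pseudocount of 10, a minimum of 30 cells and a minimum of 50 CPM. Scaling by total counts alone was added after the data had been seen.

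The procedure was tested on simulated counts in which 200 genes were changed by a known factor. They were drawn from a negative binomial distribution with the mean of both arms per library and the dispersion that edgeR fitted. The simulation thus obeys the model of the test, and real counts may not. At a simulated fold of 4, between 81.2% (pharyngeal neurons) and 100% (AWC) of these genes were recovered. At a simulated fold of 2 the share was between 13.6% (neurons against non-neuronal cells) and 69.0% (AWC). False calls made up 1.53% to 4.12% of calls in 5 comparisons, and 22.5% in the comparison of pharyngeal neurons, where they made up 9.35% with RLE. There the median log2 fold change of the unchanged genes was −0.41 with TMM and −0.05 with RLE, against a simulated value of 0.

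Left out of the comparisons were 4195 cells whose tissue the authors left unannotated or unknown. The genes tested as carried on transgenes (lin-15A, lin-15B, pha-1, rol-6, unc-119 and dpy-20), and unc-54, were left out of the named genes of the other comparisons. Genes whose promoter drives a reporter, such as cho-1, eat-4 and unc-47, stayed in, although some were higher in the libraries sorted for them. No reads were available here, so transgene transcripts could not be told from those of the chromosomal genes.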

Results

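Single-cell RNA was sequenced from 17 libraries of C. elegans, mostly L4 larvae (68% to 98% where the labels gave a share). They were sorted for reporters of all neurons (2 libraries), of unc-47, which marks GABAergic neurons (2 libraries), and of cho-1, which marks cholinergic neurons (2 libraries). The rest were sorted for 11 other markers or mixtures of markers with 1 library each. The deposited counts covered 100955 cells and 22469 genes. The authors' annotation named 70296 cells as neurons (69.6%) of 130 types, with 12 to 3189 cells and a median of 361 cells per type. Another 26464 cells were non-neuronal, among them 8076 of muscle and mesoderm, 6848 of the reproductive system, 6150 of the hypodermis, 1958 of the pharynx, 1557 of the intestine, 1293 glia, 556 of the excretory system and 26 rectal cells. The libraries held from 915347 UMIs (unc-47 replicate 1) to 20739841 UMIs (acr-2), 151210616 in all. A cell had a median of 928 UMIs and 328 genes over all libraries, and the median UMIs per cell ranged from 366 to 1681 between libraries. Of the neuron types, 127 had at least 10 cells in at least 1 library, 116 in at least 2 libraries and 63 in at least 5. Log2 fold changes are given ± SE and CPM as mean ± SD, each over the libraries of the comparison (n).

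Sorting addressed which neuron types each reporter captures. In the library sorted for ift-20, a subunit of intraflagellar transport, 96.9% of the annotated neurons were ciliated sensory types (95% Wilson interval 96.4 to 97.4%), where the pan-neuronal libraries held a mean of 14.1%. Command and related interneurons listed for nmr-1 (NMDA receptor subunit) made up 88.4% of the neurons of its library (87.0 to 89.6%), against 1.96%. The types listed for unc-86 (POU homeobox) made up 86.4% of the neurons of its library (85.0 to 87.8%), against 13.7%. In the library sorted for tph-1 and ceh-10 the listed types made up 83.4% of neurons (82.1 to 84.7%), against 0.922%, and CAN alone made up 55.9%. Glutamatergic types made up 81.9% of the neurons of the eat-4 library (81 to 83%), against 29%. Cholinergic ventral cord motor neurons made up 76.7% of the neurons of the acr-2 library (75.9 to 77.5%), against 5.35%. Pharyngeal types made up 76.2% of the neurons of the ceh-34 library (74.5 to 77.9%), against 2.50%. Of all cells, neurons made up 50.0% in the eat-4 library, 79.5% in the acr-2 library and 70.3% in the ceh-34 library. GABAergic types reached 54.5% of neurons (51.9 to 57.0%) in unc-47 replicate 1 and 29.8% (28.3 to 31.4%) in replicate 2, against 3.86%. In replicate 2 the non-target type SIA was the most frequent, at 32.2%. In the library labelled unc-3, the cholinergic cord motor neurons listed for it made up 8.53% of neurons (7.78 to 9.36%), against 6.51% and 4.20% in the pan-neuronal libraries, and AVJ (10.1%), SMD (8.80%) and AIB (7.78%) were the most frequent types. With 1 library for most sorts, these shares had no test.

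**Figure D1:**
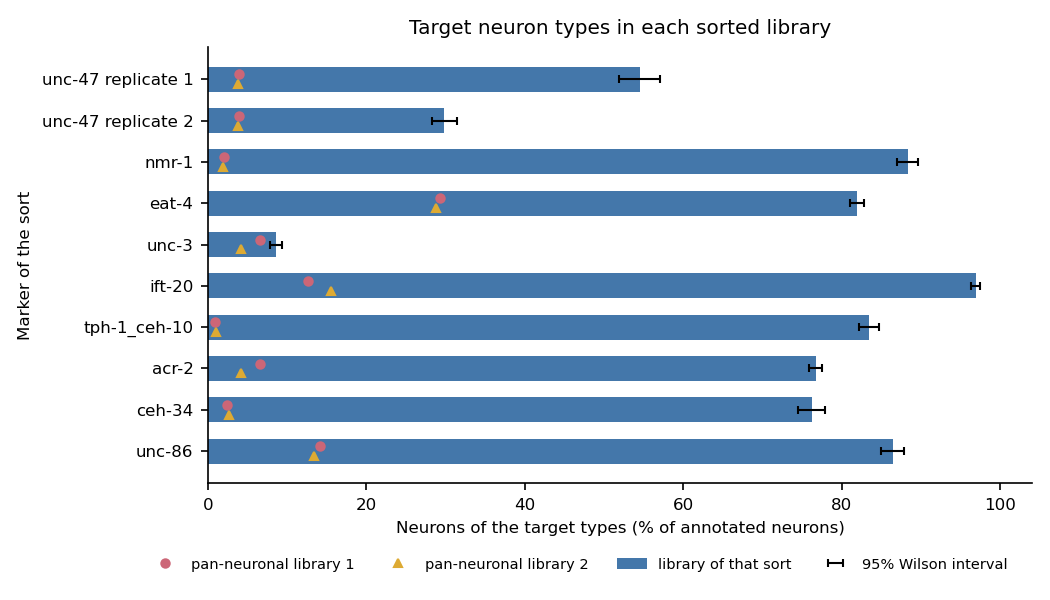
Share of annotated neurons that belong to the target types of each sort (bars, % with 95% Wilson intervals), with the same types in the pan-neuronal libraries (points). Shares were 76.2% or more in 7 libraries, 54.5% and 29.8% in the unc-47 libraries and 8.53% in the library labelled unc-3.

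Neurons were compared with the non-neuronal cells of the same libraries to find the genes that set neurons apart (n = 17 libraries). The synaptic vesicle gene rab-3 was higher in neurons (log2 fold change 5.06 ± 0.42; 554 ± 317 CPM in neurons), as was egl-3, a proprotein convertase of neuropeptides (6.06 ± 0.46). The gene with the largest rise was ins-3 (8.73 ± 0.44), an insulin-like peptide gene, followed by ins-6 (8.71 ± 0.65) and R102.2 (8.55 ± 0.70), and ins-26 (8.35 ± 0.51) and flp-27 (8.23 ± 0.93) were close behind. The genes with the largest falls were msp-59 (−10.98 ± 0.55), msp-113 (−10.63 ± 0.81) and nspa-8 (−10.54 ± 0.74), with msp-53, msp-31, msp-40 and msp-57 at −10.18 to −9.85. The msp genes encode the major sperm protein in near-identical copies that share reads, so the values of single copies are uncertain. Next came dod-6 (−10.22 ± 1.08) and ram-2 (−10.02 ± 0.76). Of 9688 genes tested, 3539 rose and 3754 fell in neurons (edgeR, adjusted p under 0.05). RLE called 4200 higher and 3311 lower, and total counts alone 2968 higher and 4556 lower. The median log2 fold change of all tested genes was −0.06 with TMM, 0.28 with RLE and −0.51 with scaling by total counts alone, and fold changes are to be read against that shift.

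All 24 synaptic vesicle and dense core vesicle genes rose in neurons, with a median log2 fold change of 4.70 (camera adjusted p = 1.01e-12, adjusted p = 0.175 with an estimated correlation), among them sbt-1, a chaperone of EGL-3 (6.02 ± 0.43), and cab-1 (5.49 ± 0.38). Of 121 neuropeptide genes tested, 106 rose and 13 fell (median 5.80; camera adjusted p = 6.63e-15, adjusted p = 0.192 with an estimated correlation). Homeobox genes had 34 higher, 3 lower and 9 not called (median 3.09; camera adjusted p = 8.82e-06, adjusted p = 0.175 with an estimated correlation), with unc-4 at 6.48 ± 0.42 and ceh-24 at 4.34 ± 0.32. Potassium channel genes had 38 higher, 1 lower and 2 not called (median 4.37; camera adjusted p = 1.09e-09, adjusted p = 0.175 with an estimated correlation), with kvs-2 at 6.49 ± 0.43 and twk-2 at 5.01 ± 0.38. Glutamate receptor genes had 13 higher, 0 lower and 1 not called (median 4.50; camera adjusted p = 2.81e-05, adjusted p = 0.192 with an estimated correlation), with glr-3 at 6.04 ± 0.54 and glr-2 at 4.66 ± 0.42. Acetylcholine receptor genes had 12 higher, 0 lower and 2 not called (median 3.06; camera adjusted p = 0.00145, adjusted p = 0.210 with an estimated correlation), with acr-12 at 5.45 ± 0.48 and acr-2 at 3.96 ± 0.37. Degenerin channel genes had 7 higher, 1 lower and 0 not called (median 4.14; camera adjusted p = 0.0311, adjusted p = 0.241 with an estimated correlation), with del-1 at 5.58 ± 0.44 and del-8 at 5.09 ± 0.50. Innexin genes went both ways, with 3 higher, 8 lower and 3 not called (median −2.90; camera adjusted p = 0.270).

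Genes of single neuron classes also stood out from non-neuronal cells. All 5 tested acetylcholine pathway genes rose (median 5.25; camera adjusted p = 0.00208, adjusted p = 0.192 with an estimated correlation), including the vesicular transporter gene unc-17 (5.25 ± 0.42). The choline transporter gene cho-1 (5.59 ± 0.47) averaged in neurons 25074 CPM in the cho-1 libraries and 120 CPM in the others. Of 4 GABA pathway genes 3 rose and none fell (median 5.53; camera adjusted p = 0.0311, adjusted p = 0.210 with an estimated correlation), with the vesicular transporter gene unc-47 at 6.99 ± 0.48 and the glutamate decarboxylase gene unc-25 at 5.87 ± 0.65. Monoamine pathway genes had 3 higher, 0 lower and 3 not called (median 1.68; camera adjusted p = 0.269). Of 50 intraflagellar transport and cilium genes 49 rose (median 5.67; camera adjusted p = 1.51e-14, adjusted p = 0.210 with an estimated correlation), such as ift-74 (6.74 ± 0.36) and tbb-4 (6.11 ± 0.37). All 9 receptor guanylyl cyclase genes tested rose (median 4.33; camera adjusted p = 0.00307, adjusted p = 0.192 with an estimated correlation), such as gcy-11 (7.34 ± 0.79) and gcy-37 (5.97 ± 0.70). Of 1200 chemosensory GPCR genes 20 passed the filter on low counts, with 14 higher, 4 lower and 2 not called (median 4.38; camera adjusted p = 0.00259, adjusted p = 0.210 with an estimated correlation). sri-48 reached 6.80 ± 0.46 and srab-14 5.89 ± 0.49. All 8 touch receptor neuron genes rose (median 5.59; camera adjusted p = 0.00167, adjusted p = 0.210 with an estimated correlation), including the tubulin gene mec-12 (5.92 ± 0.56) and mec-1 (5.65 ± 0.53).

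Heat shock genes had 10 higher, 1 lower and 2 not called in neurons (median 3.11; camera adjusted p = 0.00307, adjusted p = 0.241 with an estimated correlation). Their summed level was 110466 ± 108087 CPM against 19654 ± 20941 CPM, higher in neurons in 17 of 17 libraries. F44E5.5 (3.49 ± 0.36) and hsp-16.48 (3.11 ± 0.32) were the members with the smallest p, but both share reads with near-identical copies, so the value of each copy is uncertain. Ribosomal protein genes had 1 higher, 70 lower and 8 not called (median −1.03; camera adjusted p = 0.000102, adjusted p = 0.554 with an estimated correlation), with rpl-11.1 at −4.45 ± 0.44 and rpl-25.2 at −3.39 ± 0.39. Mitochondrially encoded genes had 0 higher, 0 lower and 12 not called with TMM (median 0.20; camera adjusted p = 0.605), 7 higher and 0 lower with RLE (median 0.49), and 0 higher and 3 lower with total counts alone (median −0.34).

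Marker genes of other cells do not test the annotation, whose method was not stated, since it could rest on the same genes. Of 93 cuticle collagen genes 90 fell (median −7.46; camera adjusted p = 1.53e-25, adjusted p = 0.175 with an estimated correlation), such as col-154 (−8.21 ± 0.47), and their summed level was 349 ± 125 CPM against 78483 ± 58589 CPM. All 13 germline genes fell (median −6.22; camera adjusted p = 9.38e-07, adjusted p = 0.192 with an estimated correlation), such as the P granule gene pgl-1 (−8.21 ± 0.46). Body wall muscle genes had 0 higher, 11 lower and 2 not called (median −5.19; camera adjusted p = 0.000404, adjusted p = 0.241 with an estimated correlation), with the troponin C gene pat-10 at −7.38 ± 0.64 and the myosin light chain gene mlc-2 at −6.25 ± 0.50. All 6 pharyngeal muscle and gland genes fell (median −6.50; camera adjusted p = 0.00581, adjusted p = 0.222 with an estimated correlation), such as phat-4 (−9.56 ± 0.96). Both tested intestine genes and the 1 tested coelomocyte gene fell. Glia genes had 1 higher, 1 lower and 1 not called (camera adjusted p = 0.996), and their summed level was 258 ± 334 CPM against 178 ± 121 CPM. Adjusted over the list alone, the counts were the same in this comparison except for homeobox genes (35 higher and 3 lower), ribosomal protein genes (1 higher and 71 lower), acetylcholine receptor genes (14 higher and 0 lower) and heat shock genes (11 higher and 1 lower). None of the 19 lists that camera called in this comparison kept its call with an estimated correlation.

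**Figure D2:**
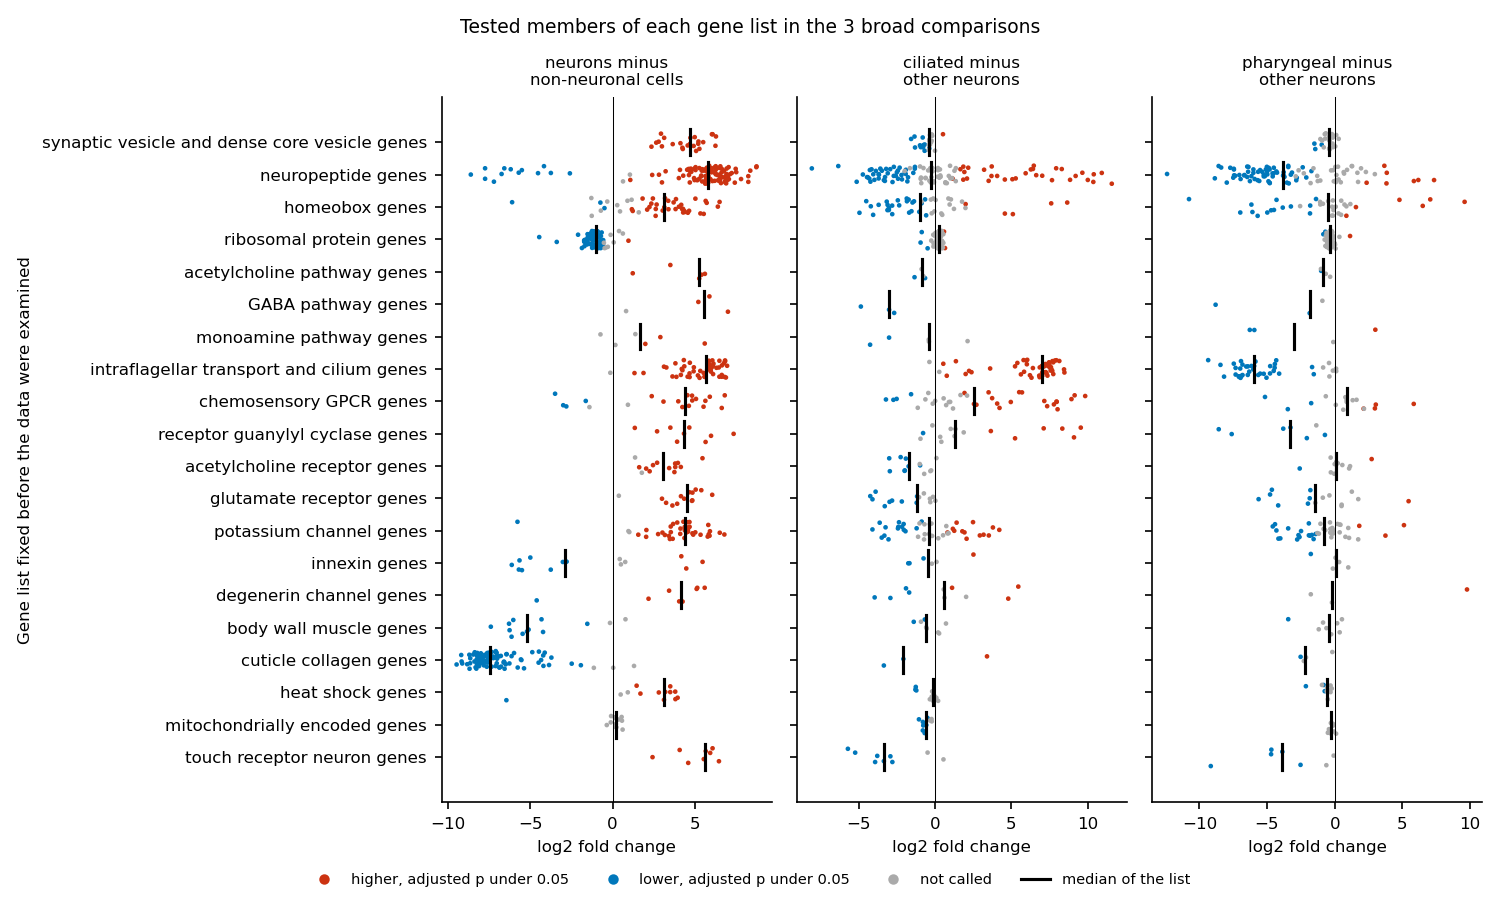
Log2 fold change of each tested member of the gene lists in the comparisons of neurons with non-neuronal cells, ciliated with other neurons and pharyngeal with other neurons (points are genes, black lines are list medians, colour marks calls at an adjusted p under 0.05). Intraflagellar transport and cilium genes had medians of 5.67, 7.03 and −5.95 in the 3 comparisons.

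Ciliated sensory neurons, which bear the cilia that detect odours, tastes and touch, were compared with all other neurons to find what distinguishes them (n = 16 libraries). Cilium genes separated the arms: of 52 intraflagellar transport and cilium genes tested, 50 were higher in ciliated neurons and 2 were not called (median 7.03; camera adjusted p = 1.42e-55, adjusted p = 0.0307 with an estimated correlation). Among them were ift-20 (7.58 ± 0.61; 499 ± 192 CPM against 14.3 ± 41.5 CPM), che-11, a subunit of the transport complex (8.46 ± 0.35), and the dynein light chain gene dylt-2 (7.37 ± 0.29). The largest rises were R102.2 (12.47 ± 0.86), F23D12.3 (11.78 ± 0.75) and the insulin-like genes ins-6 (11.59 ± 0.92), ins-26 (10.93 ± 1.15) and ins-14 (10.41 ± 0.55). The largest falls were nlp-17 (−8.10 ± 1.35), zig-2 (−6.44 ± 0.85), flp-8 (−6.36 ± 0.95) and C25G6.4 (−6.16 ± 0.55), and eya-1, an Eyes absent homologue, fell too (−5.30 ± 0.45). In all, 1492 of 7476 genes rose and 1595 fell (edgeR, adjusted p under 0.05), and the median log2 fold change was −0.15 with TMM, −0.19 with RLE and −0.23 with total counts alone.

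Of 35 chemosensory GPCR genes tested, 19 rose and 4 fell (median 2.55; camera adjusted p = 1.26e-05, adjusted p = 0.221 with an estimated correlation), with str-260 at 7.98 ± 0.41 and srb-18 at 7.96 ± 0.42. Receptor guanylyl cyclase genes had 6 higher, 1 lower and 8 not called (median 1.33; camera adjusted p = 0.000288, adjusted p = 0.177 with an estimated correlation), with daf-11 at 8.34 ± 0.42 and gcy-9 at 7.12 ± 0.37. Acetylcholine receptor genes had 0 higher, 8 lower and 5 not called (median −1.74; camera adjusted p = 0.00261, adjusted p = 0.177 with an estimated correlation), with acr-2 at −2.98 ± 0.36 and unc-38 at −1.74 ± 0.21. Glutamate receptor genes had 0 higher, 9 lower and 6 not called (median −1.22; camera adjusted p = 0.000264, adjusted p = 0.177 with an estimated correlation), with glr-1 at −4.12 ± 0.41 and nmr-2 at −4.26 ± 0.40. All 3 tested GABA pathway genes fell (median −3.03; camera adjusted p = 0.0156, adjusted p = 0.192 with an estimated correlation), with unc-25 at −4.88 ± 0.73 and unc-46 at −3.03 ± 0.38. Homeobox genes had 5 higher, 25 lower and 14 not called (median −0.97; camera adjusted p = 0.0300, adjusted p = 0.221 with an estimated correlation), with unc-4 at −4.97 ± 0.41 and tab-1 at −4.53 ± 0.46. Synaptic vesicle and dense core vesicle genes had 1 higher, 11 lower and 12 not called (median −0.41; camera adjusted p = 0.0161, adjusted p = 0.553 with an estimated correlation), with the kinesin gene unc-104 at −1.36 ± 0.18. Touch receptor neuron genes had 0 higher, 7 lower and 2 not called (median −3.37; camera adjusted p = 0.0156, adjusted p = 0.404 with an estimated correlation), with mec-12 at −3.37 ± 0.38. The vesicular glutamate transporter gene eat-4 (−0.41 ± 0.46, adjusted p = 0.508) and unc-17 (−0.78 ± 0.35, adjusted p = 0.0835) did not pass.

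Neuropeptide genes went both ways in ciliated neurons, with 32 higher, 42 lower and 36 not called; their median was −0.28 and their mean 0.46, of opposite sign (camera adjusted p = 0.648). Of the other lists, potassium channel genes had 13 higher, 15 lower and 14 not called, degenerin channel genes 3 higher, 4 lower and 3 not called and ribosomal protein genes 2 higher, 3 lower and 74 not called. Camera called none of these, nor acetylcholine pathway genes (0 higher, 2 lower and 2 not called), mitochondrially encoded genes (0 higher, 9 lower and 3 not called) or body wall muscle genes (0 higher, 2 lower and 6 not called). Heat shock genes had 0 higher, 3 lower and 9 not called, and their summed level was lower in ciliated neurons in 16 of 16 libraries (85629 ± 84912 CPM against 121373 ± 109611 CPM). Adjusted over the list alone, counts differed for neuropeptide genes (33 higher and 43 lower), homeobox genes (7 higher and 25 lower), intraflagellar transport and cilium genes (50 higher and 1 lower) and chemosensory GPCR genes (20 higher and 4 lower). They also differed for acetylcholine receptor genes (0 higher and 9 lower), potassium channel genes (14 higher and 18 lower), ribosomal protein genes (0 higher and 1 lower) and acetylcholine pathway genes (0 higher and 4 lower). The summed level of pharyngeal muscle and gland genes was higher in ciliated neurons in 15 of 16 libraries (84.9 ± 67.6 CPM against 12.8 ± 10.1 CPM), with phat-3 at 62.4 ± 59.6 CPM against 2.41 ± 2.80 CPM, and that of intestine genes in 13 of 16 (13.4 ± 10.2 CPM against 3.65 ± 2.61 CPM). For the other marker lists the level was higher in 10 (glia), 8 (cuticle collagen), 7 (germline), 6 (coelomocyte) and 3 (body wall muscle) of 16 libraries. With an estimated correlation the call of the cilium genes held and the other 8 calls did not.

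Pharyngeal neurons, which form the small nervous system of the feeding organ, were compared with all other neurons (n = 11 libraries). The sine oculis homeobox gene ceh-34, which marks this class, was higher (9.60 ± 0.59; 1294 ± 408 CPM against 2.20 ± 3.76 CPM), as was eya-1 (8.47 ± 0.49), whose product binds proteins of that family. The largest rises were trh-1, a gene of a peptide related to thyrotropin-releasing hormone (10.04 ± 0.83), Y53G8AL.4 (10.02 ± 0.51), the degenerin channel gene degt-1 (9.77 ± 0.75) and pho-8 (9.61 ± 0.83). Other peptide or secreted protein genes that rose were lury-1 (9.07 ± 1.14) and spp-28 (8.59 ± 0.61). No UMI of ins-6 was found in pharyngeal neurons, so it was at least 1028-fold lower there, and C12D5.4 and ceh-57 were at least 403-fold and 98.5-fold lower. Without the ceh-34 library these 3 bounds were 508-fold, 173-fold and 46.5-fold. R102.2 fell (−9.48 ± 0.70), as did the tubulin acetyltransferase gene mec-17 (−9.16 ± 0.68) and B0294.1 (−9.13 ± 0.74). In the other neurons arl-3, a small GTPase of cilia with 3 UMIs in pharyngeal neurons, was 446 times (exact 95% interval 152 to 2161) as high, and unc-25 993 times (exact 95% interval 339.8 to 4816). The same 2 ratios without that library were 205 and 457. The serotonin synthesis gene tph-1 rose (3.00 ± 0.64, edgeR adjusted p = 0.00156, higher in 8 and lower in 2 of 11 libraries). The types in the pharyngeal arm differed by library. NSM, a target type of the tph-1 sort, had 510 cells in the nlp-13 and ceh-2 library, 50 in the tph-1 and ceh-10 library and at most 6 in any other. Whether tph-1 rose in other pharyngeal types was not tested. eat-4 (0.08 ± 0.49, adjusted p = 0.948) and unc-17 (−0.66 ± 0.29, adjusted p = 0.126) did not pass.

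Of 6727 genes tested, 260 rose and 1216 fell in pharyngeal neurons (edgeR, adjusted p under 0.05). This balance depended on the scaling: RLE called 342 higher and 953 lower, and total counts alone 439 higher and 798 lower. In simulated data of this comparison 22.5% of calls were false with TMM and 9.35% with RLE. The median log2 fold change was −0.30 with TMM, −0.07 with RLE and 0.11 with total counts alone. Of 97 neuropeptide genes 7 rose and 62 fell (median −3.79, or −3.79 with the gene at 0 in one arm at its bound; camera adjusted p = 8.57e-13, adjusted p = 0.0792 with an estimated correlation). Of 41 intraflagellar transport and cilium genes 35 fell and none rose (median −5.95; camera adjusted p = 6.50e-19, adjusted p = 0.248 with an estimated correlation), such as ifta-2 (−7.32 ± 0.48). Receptor guanylyl cyclase genes had 0 higher, 6 lower and 1 not called (median −3.27; camera adjusted p = 0.0145, adjusted p = 0.273 with an estimated correlation), with gcy-11 at −8.57 ± 1.16 and gcy-33 at −7.61 ± 0.51. Touch receptor neuron genes had 0 higher, 5 lower and 2 not called (median −3.87; camera adjusted p = 0.00113, adjusted p = 0.248 with an estimated correlation), with mec-9 at −3.87 ± 0.43. GABA pathway genes had 0 higher, 2 lower and 1 not called (median −1.85; camera adjusted p = 0.0371, adjusted p = 0.270 with an estimated correlation), with unc-46 at −1.85 ± 0.47. Chemosensory GPCR genes had 4 higher, 3 lower and 9 not called (median 0.88; camera adjusted p = 0.00377, adjusted p = 0.0792 with an estimated correlation), with srv-7 at 5.84 ± 0.73 and srx-45 at 2.97 ± 0.43.

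Degenerin channel genes had 1 higher, 0 lower and 2 not called in pharyngeal neurons, with a median of −0.21 (0.17 with total counts alone), a mean of 2.60 and a camera direction that followed the mean (camera adjusted p = 0.0411, adjusted p = 0.270 with an estimated correlation). Homeobox genes had 6 higher, 14 lower and 17 not called, potassium channel genes 3 higher, 16 lower and 21 not called and glutamate receptor genes 1 higher, 7 lower and 7 not called. Monoamine pathway genes had 1 higher, 2 lower and 1 not called and synaptic vesicle and dense core vesicle genes 0 higher, 3 lower and 21 not called (median −0.40 with TMM, 0.05 with total counts alone), and camera called none of these 5 lists. Adjusted over the list alone, counts differed for neuropeptide genes (10 higher and 65 lower), homeobox genes (6 higher and 16 lower), intraflagellar transport and cilium genes (0 higher and 36 lower) and chemosensory GPCR genes (5 higher and 3 lower). Other lists that differed were receptor guanylyl cyclase genes (0 higher and 7 lower), glutamate receptor genes (2 higher and 9 lower), potassium channel genes (4 higher and 16 lower) and innexin genes (1 higher and 1 lower). So did degenerin channel genes (1 higher and 1 lower), ribosomal protein genes (0 higher and 0 lower), cuticle collagen genes (0 higher and 2 lower) and glia genes (0 higher and 2 lower). None of the 7 lists called by camera kept its call with an estimated correlation. The summed level of glia genes was 112 ± 80.9 CPM against 346 ± 395 CPM, higher in pharyngeal neurons in 1 of 11 libraries, and that of germline genes 147 ± 222 CPM against 42.6 ± 19.9 CPM, higher in 7 of 11. Of the other marker lists, the level was higher in 9 of 11 libraries for pharyngeal muscle and gland genes, 8 for cuticle collagen genes, and 6 for body wall muscle, intestine and coelomocyte genes alike.

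Cholinergic and GABAergic motor neurons of the ventral cord excite and inhibit body wall muscle, and were compared to find the genes that part them (n = 7 libraries). GABAergic neurons held the genes of their transmitter: unc-25 was at 57666 ± 13204 CPM there (log2 fold change of cholinergic over GABAergic −12.21 ± 1.72), and in cholinergic neurons at 5320 CPM in unc-47 replicate 2 and 0 to 49 CPM in the other 6 libraries. unc-47 differed by −7.50 ± 0.64 and unc-46 by −8.73 ± 0.88. The homeobox gene unc-30, a regulator of GABAergic identity, fell alike (−9.74 ± 0.90), with ttr-39 (−12.30 ± 1.72), F14B8.5 (−10.62 ± 0.45), the peptide gene nlp-78 (−9.27 ± 1.03) and, without the filter on low counts, the nuclear receptor gene unc-55 (−3.25 ± 0.58). Cholinergic neurons had more unc-17 (4.12 ± 0.56), unc-3, a regulator of cholinergic identity (4.27 ± 0.55), the receptor gene acr-2 (4.26 ± 0.55) and the homeobox gene unc-4 (4.38 ± 0.69). Without the filter on low counts cho-1 (4.55 ± 0.57) and the TGF-beta family gene unc-129 (3.77 ± 0.59) were higher too. vab-7, with 1 UMI in GABAergic neurons, was 76.0 times (exact 95% interval 13.6 to 3004) as high in cholinergic neurons, and 13.3 times without the acr-2 library. The largest rises were T26C5.5 (5.58 ± 0.82), Y119C1B.3 (5.48 ± 0.60), the peptide gene flp-18 (5.11 ± 0.38) and F08D12.12 (5.04 ± 0.47). The potassium channel gene twk-29 (4.80 ± 0.55), the immunoglobulin domain gene oig-5 (4.93 ± 0.63) and nlp-21 (4.75 ± 0.74) rose as well.

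Of 920 genes tested, 245 were called, of which 126 fell and the others rose in cholinergic neurons (edgeR, adjusted p under 0.05), and the median log2 fold change was −0.01 with TMM, 0.08 with RLE and −0.04 with total counts alone. Of 13 neuropeptide genes 8 rose and 5 fell (median 2.13; camera adjusted p = 0.0480, adjusted p = 0.796 with an estimated correlation), among them nlp-9 (4.35 ± 0.43). All 3 tested GABA pathway genes fell (median −8.73; camera adjusted p = 0.000582, adjusted p = 0.389 with an estimated correlation). Synaptic vesicle and dense core vesicle genes had 2 higher, 3 lower and 13 not called, homeobox genes 3 higher, 1 lower and 2 not called and potassium channel genes 4 higher, 2 lower and 3 not called, and none of the 10 heat shock genes or 74 ribosomal protein genes was called. Adjusted over the list alone, counts differed for synaptic vesicle and dense core vesicle genes (3 higher and 3 lower). In unc-47 replicate 2, unc-25 and ttr-39 differed less between the arms than in the other 6 libraries. The summed level of glia genes was higher in cholinergic neurons in 7 of 7 libraries (2108 ± 1652 CPM against 223 ± 486 CPM), nearly all of it hlh-17 (2015 ± 1685 CPM against 166 ± 417 CPM).

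ASEL and ASER are the left and right members of a pair of taste neurons that express different receptors (n = 3 libraries). Genes of receptor guanylyl cyclases, which act as salt receptors, parted them: gcy-14 was at least 256-fold lower in ASER, where it had no UMI, gcy-17 at least 77.5-fold, gcy-7 at least 61.2-fold and gcy-20 at least 48.8-fold. gcy-22 was at least 36.8-fold higher in ASER, with no UMI in ASEL. Without the filter on low counts gcy-3 and gcy-5 were at least 10.8-fold and 7.37-fold higher in ASER. Without the eat-4 library these bounds were 77.7-fold (gcy-14), 26.4-fold (gcy-17), 18.0-fold (gcy-7), 22.3-fold (gcy-20), 15.0-fold (gcy-22), 3.46-fold (gcy-3) and 3.33-fold (gcy-5). The LIM homeobox gene lim-6 was lower in ASER (−6.80 ± 0.69; 3535 ± 623 CPM in ASEL), and gcy-6, with 2 UMIs in ASER, was 91.6 times (exact 95% interval 24.6 to 768) as high in ASEL. For the regulators die-1 and cog-1, in the fit without the filter, die-1 was 33.6 times (exact 95% interval 8.59 to 289) as high in ASEL, and 16.3 times without the ift-20 library. The cog-1 ratio, on 5 UMIs in ASER and 1 in ASEL, was not called (adjusted p = 0.987). Peptide genes called higher in ASER included nlp-60 (at least 40.5-fold, 19.5-fold without the eat-4 library), nlp-5 (at least 33.3-fold, 12.8-fold without it), ins-3 (7.03 ± 0.73) and nlp-57 (7.10 ± 0.90). Also at 0 in ASEL were K07C5.9 (at least 77.3-fold higher in ASER, 38.3-fold without the eat-4 library) and C08E8.5 (at least 48.2-fold, 19.6-fold without pan-neuronal replicate 2). frpr-13, a gene of the FMRFamide peptide receptor family (−6.35 ± 0.62), and F45D3.3 (−6.24 ± 0.53) fell.

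Of 611 genes tested, 36 rose and 34 fell in ASER (edgeR, adjusted p under 0.05), and the median log2 fold change was 0.10 with TMM, 0.07 with RLE and 0.26 with total counts alone. Of 39 neuropeptide genes 12 rose and 4 fell (median 1.59, or 1.59 with genes at 0 in one arm at their bound; camera adjusted p = 0.000115, adjusted p = 0.313 with an estimated correlation). Of 7 receptor guanylyl cyclase genes 2 rose and 5 fell (median −8.16, or −5.93 with genes at 0 in one arm at their bound; camera adjusted p = 2.11e-05, adjusted p = 0.324 with an estimated correlation). Heat shock genes had 0 higher, 3 lower and 5 not called (median −0.69, camera adjusted p = 0.0331, adjusted p = 0.717 with an estimated correlation). Among them were hsp-70 at −2.46 ± 0.31 and F44E5.5 at −1.23 ± 0.24. F44E5.5 shares reads with near-identical copies, so its single value is uncertain, and for hsp-70 such sharing was not tested. The summed level of heat shock genes was lower in ASER in 3 of 3 libraries (55184 ± 47671 CPM against 103509 ± 74820.1 CPM). Adjusted over the list alone, 15 neuropeptide genes were higher and 7 lower, and 1 chemosensory GPCR gene was higher. Without the ift-20 library edgeR called 0 genes, with 63 higher and 56 lower at an unadjusted p under 0.05. Without pan-neuronal replicate 2 it called 136.

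AWC_ON and AWC_OFF are the members of a pair of odour sensing neurons with different receptors (n = 4 libraries). Single chemosensory GPCR genes differed in both directions: srt-28 was at least 330.4-fold higher in AWC_ON and srx-50 at least 77.6-fold, both with no UMI in AWC_OFF (208-fold and 47.1-fold without the eat-4 library), and srt-42 rose (7.74 ± 0.52). In the other direction srx-2 (1287 ± 237 CPM in AWC_OFF) and srsx-3, a marker of AWC_OFF, had no UMI in AWC_ON, where srsx-3 was at least 88.8-fold lower (54.1-fold without the ift-20 library). srsx-5, with 2 UMIs there, was 401 times (exact 95% interval 111 to 3316) as high in AWC_OFF, and 256 times without the eat-4 library. str-2, a marker of AWC_ON, was at least 7.01-fold higher without the filter on low counts, on 16 UMIs against 0 (3.56-fold without pan-neuronal replicate 1). ntc-1, the gene of a peptide related to vasopressin and oxytocin, was at 13915 ± 2554 CPM against 25.6 ± 51.1 CPM (9.41 ± 0.73). The transcription factor gene nsy-7 was 157 times (exact 95% interval 53.4 to 763) as high in AWC_ON, and flp-21 (4.07 ± 0.64) rose. Higher in AWC_OFF were dac-1, a Dachshund homologue (−5.55 ± 0.47), and the peptide genes ins-30 (−4.80 ± 0.50) and nlp-35 (−4.14 ± 0.53). hsp-70 fell too (−5.35 ± 0.94), and whether it shares reads with similar genes was not tested.

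Of 485 genes tested, 34 rose and 26 fell in AWC_ON (edgeR, adjusted p under 0.05), and the median log2 fold change was 0.01 with TMM, 0.01 with RLE and −0.07 with total counts alone. Of 29 neuropeptide genes 7 rose and 3 fell (camera adjusted p = 0.0541), and of 8 chemosensory GPCR genes 3 rose and 3 fell (camera adjusted p = 0.988). Ribosomal protein genes had 2 higher, 0 lower and 69 not called (median 0.36; camera adjusted p = 0.0130, adjusted p = 0.809 with an estimated correlation), with rla-0 at 1.36 ± 0.25 and rpl-27 at 0.76 ± 0.18. Adjusted over the list alone, neuropeptide genes had 9 higher and 3 lower, chemosensory GPCR genes 3 higher and 4 lower and ribosomal protein genes 0 in either direction. Receptor guanylyl cyclase genes were at 0 higher and 1 lower, potassium channel genes at 0 higher and 1 lower and heat shock genes at 2 higher and 2 lower. Without pan-neuronal replicate 1 edgeR called 34 genes, without the ift-20 library 36, and without the eat-4 library 41.

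**Figure D3:**
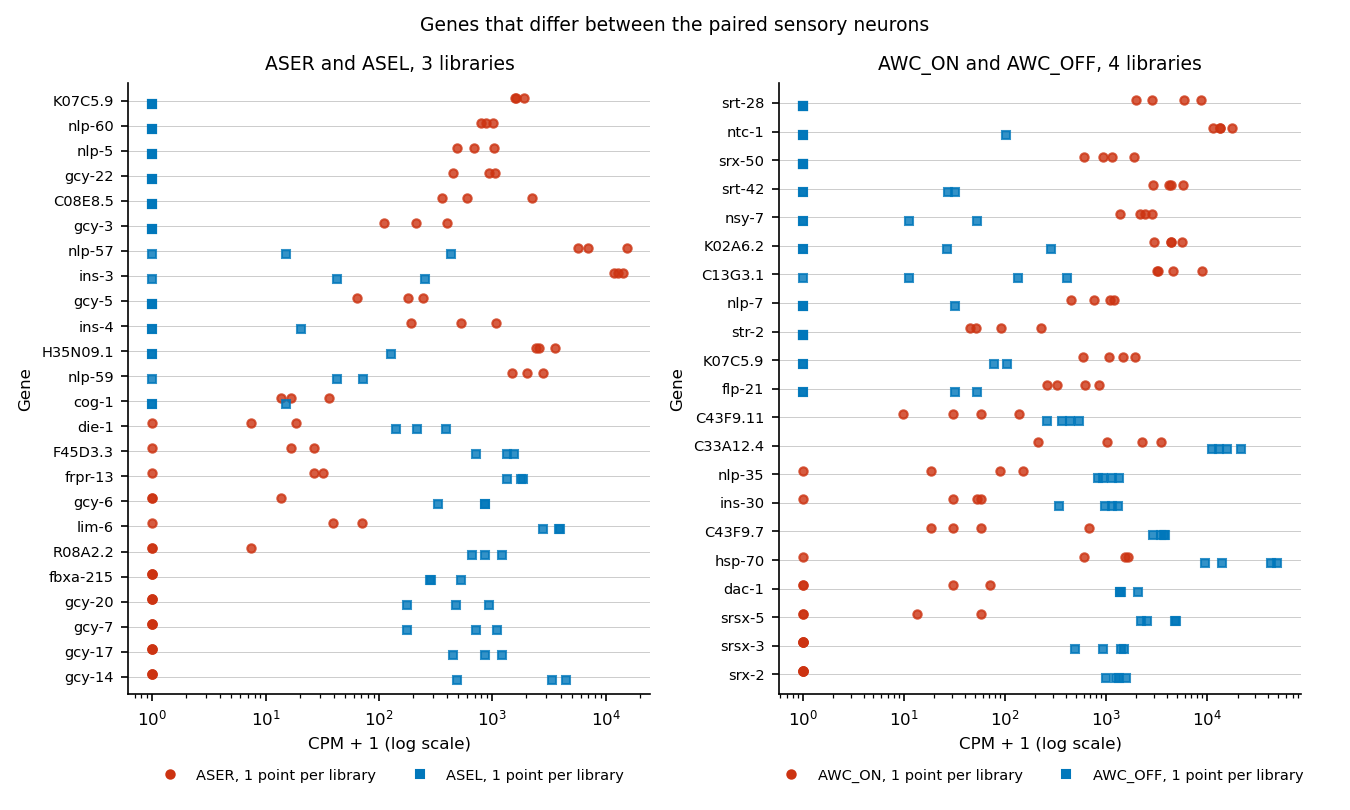
Level of the named genes in ASER and ASEL (left, 3 libraries) and in AWC_ON and AWC_OFF (right, 4 libraries), as CPM + 1 on a log axis with 1 point per library and arm. Points at 1 are libraries with no UMI, as for gcy-14 in ASER and srt-28 in AWC_OFF.

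Specificity over 127 neuron types, with stressed RIV and SMD cells as types of their own, was set against random lists of similar mean expression. The median tau of all 17600 scored genes was 0.898, so a list above its random lists can still lie below the median gene. Intestine genes, markers of other cells, had 0.969 within their random range, so tau alone does not rank the families. Neuropeptide genes had a median tau of 0.834, above the random lists (median 0.496), and homeobox genes 0.903 (random 0.705). Receptor guanylyl cyclase genes reached 0.949 (random 0.767), monoamine pathway genes 0.913 (random 0.567), degenerin channel genes 0.958 (random 0.796) and chemosensory GPCR genes 0.987 (random 0.965). Also above their random lists were genes of intraflagellar transport and cilia (0.788), of the GABA pathway (0.808), of acetylcholine receptors (0.856), glutamate receptors (0.791) and potassium channels (0.789), and touch receptor neuron genes (0.779). Below them were ribosomal protein genes (0.182), mitochondrially encoded genes (0.175), heat shock genes (0.238), synaptic vesicle and dense core vesicle genes (0.277) and cuticle collagen genes (0.909, random 0.943). Acetylcholine pathway genes (0.611) and innexin genes (0.924) lay within the random range, with the 6 lists of markers of other cells that are not collagens. In all, 12 of 25 lists lay above and 5 below the range from the 2.5 to the 97.5 percentile of 10000 random lists.

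Single types devoted large parts of their RNA to peptides. Neuropeptide genes took 59.4% of the UMIs of AVK, the highest of 127 types, where flp-1 was at 518010.2 ± 60692 CPM (n = 3 libraries), and a median of 9.87% over types. In RIS, a neuron of sleep, flp-11 was at 414161 ± 73932 CPM (n = 2), and in PVQ nlp-17 was at 402093 ± 88809.6 CPM (n = 6). Among homeobox genes, ceh-9 was at 10625 ± 4754 CPM in SAA (n = 4) and mec-3 at 8247 ± 2629 CPM in FLP (n = 4). The oxygen sensing guanylyl cyclase gene gcy-33 was at 63842 ± 28284 CPM in PQR (n = 3), and the diacetyl receptor gene odr-10 at 2823 ± 774 CPM in AWA (n = 8). These 7 genes were chosen after their values were seen. A type had 9 to 70 neuropeptide genes at 50 CPM or more, 1 to 14 homeobox genes and 0 to 141 chemosensory GPCR genes, with medians of 28, 6 and 3. In a type with few cells 1 UMI can exceed 50 CPM, so these counts depend on depth and need not be genes that the type expresses.

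**Figure D4:**
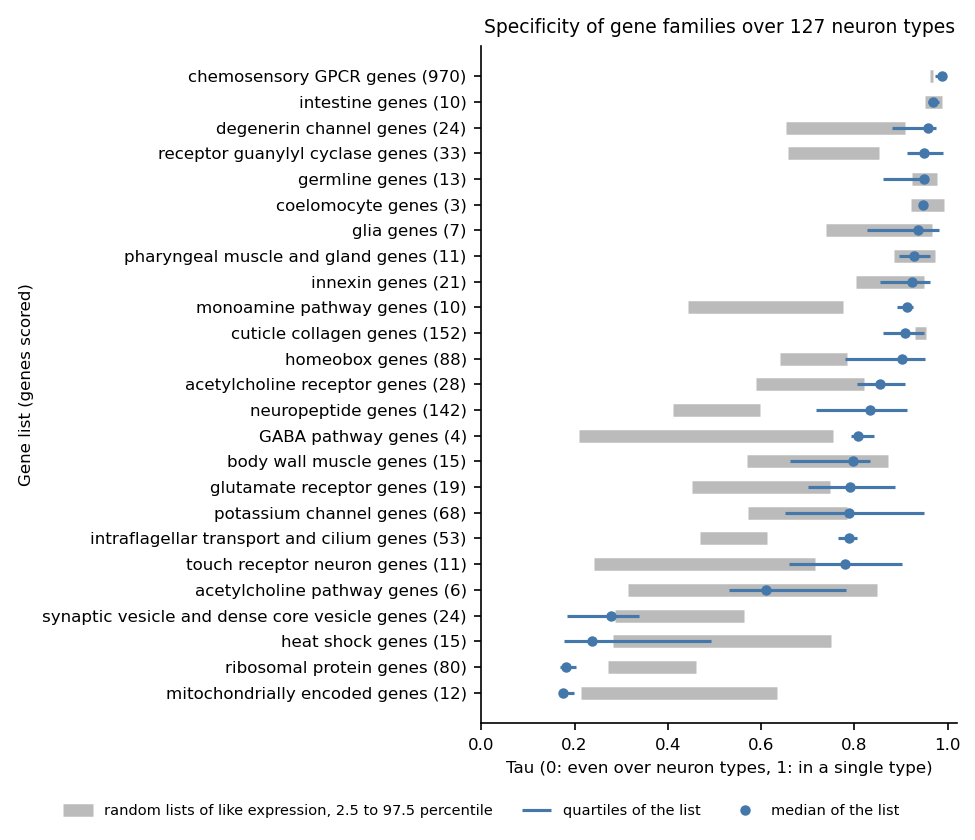
Median tau of each gene list over 127 neuron types (points, with quartiles of the list as lines) and the range of medians of 10000 random lists of similar expression (grey, 2.5 to 97.5 percentile). Neuropeptide genes (0.834) lie above their range and ribosomal protein genes (0.182) below theirs.

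Genes that mark the transgenes were compared between libraries whose strain label names them and the others, since a strain's extra copies can add transcripts. In carriers lin-15A was 2.62 higher (difference of log2 deviations; 546 against 9.35 CPM over neuron types, 7 against 10 libraries; two-sided exact permutation p = 1.54e-04, adjusted p = 4.63e-04), and lin-15B 2.82 higher (468 against 13.8 CPM; exact p = 1.03e-04, adjusted p = 4.63e-04). Each of these genes was above all non-carriers in 6 of 7 carriers. The permutation treated libraries as independent. Both unc-47 libraries are carriers from 1 sort, and the pan-neuronal and the cho-1 libraries are non-carriers with 2 libraries of 1 sort each. The permutation p may therefore be too small. pha-1 was 3.14 higher in its carriers (45.0 against 1.68 CPM, 2 against 15 libraries; exact p = 0.00735, the smallest possible, adjusted p = 0.0110). rol-6, the gene of a cuticle collagen used as a dominant marker, was 5.67 higher (726 against 2.28 CPM; exact p = 0.00735, adjusted p = 0.0110). unc-119 was 2.33 higher (556 against 108 CPM, exact p = 0.0294, adjusted p = 0.0353), and 2.84 higher without the 2 libraries that mix strains, which leaves 1 carrier against 14 libraries. Both unc-119 carriers were version 3 libraries, with deviations of 2.63 and 1.88. Version 3 libraries without it lay at 1.04 to 2.14, and version 2 libraries at −2.77 to 0.05. The permutation test took no account of chemistry, so the unc-119 difference cannot be put down to the transgene. dpy-20 was at 3222 CPM in its only carrier and 25.3 CPM in the other 16 libraries, where the smallest exact p is 0.0588. Of 19 genes whose promoter drove a reporter, 7 ranked first among the 17 libraries in a library sorted for them, by the same deviation, which adjusts for neuron type: cho-1, eat-4, unc-53, unc-47, nmr-1, ceh-10 and acr-2. The deviation was 5.38 for cho-1 (mean of 2 libraries, at most 0.50 in the others) and 1.16 for nmr-1 (at most 0.06).

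**Figure D5:**
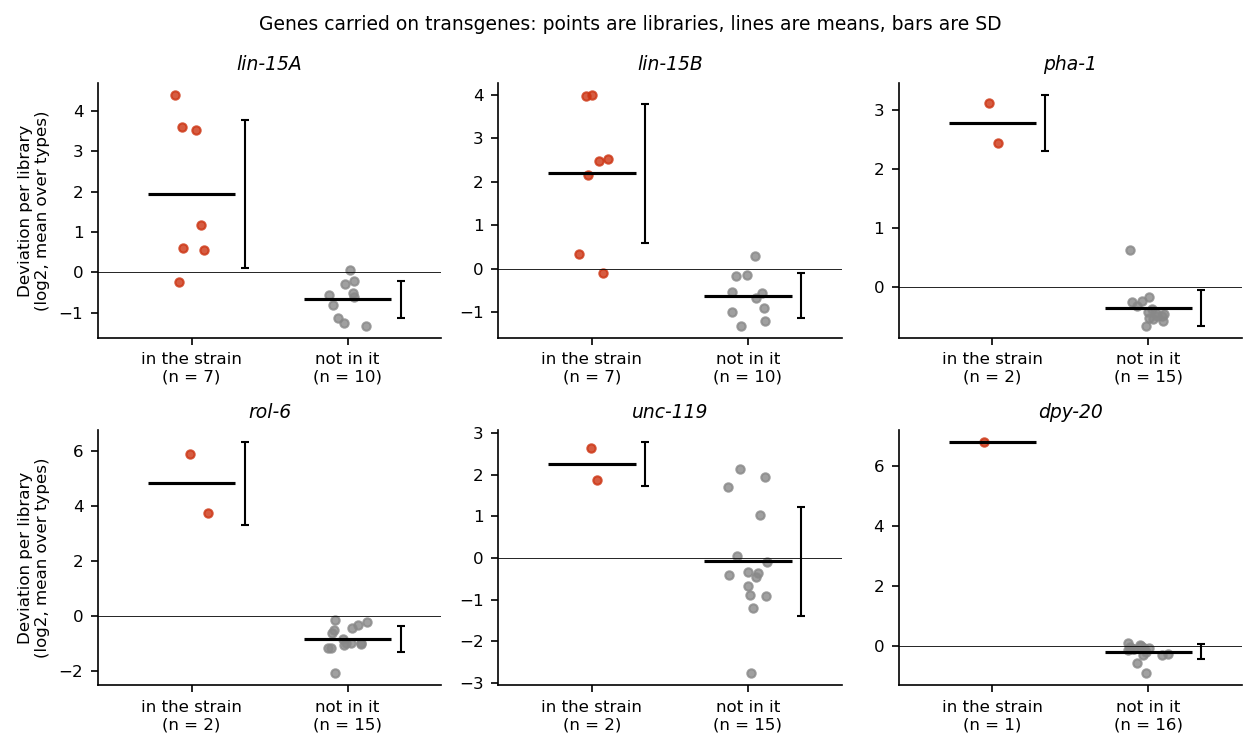
Deviation of each library from the mean of its neuron types (log2, averaged over types) for 6 genes carried on transgenes, in libraries whose strain label names the gene and in the others (points are libraries, lines are means, bars are SD). The differences of the means are 2.62 (lin-15A), 2.82 (lin-15B), 3.14 (pha-1), 5.67 (rol-6), 2.33 (unc-119) and 7.01 (dpy-20).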

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

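No test in this part was chosen after its result was seen. In the 4195 cells that the authors left without an annotated tissue, with a median of 95 UMIs per cell, synaptic vesicle and dense core vesicle genes summed to 10510 CPM, against 24654 CPM in neurons and 548 CPM in non-neuronal cells. Germline genes summed to 89.3 CPM there (54.9 CPM in neurons, 1013 CPM in non-neuronal cells). Cuticle collagen genes summed to 7744 CPM (356 CPM in neurons, 28457 CPM in non-neuronal cells). Mitochondrially encoded genes summed to 48489 CPM, against 16352 CPM in neurons and 16594 CPM in non-neuronal cells. These cells entered no comparison. The sums are listed because data outside the comparisons held counts above the 2.23 CPM that a count of 0 allows, which shows only that transcripts of these lists were present, not where they came from.

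A gap test for a library far from the others, run on the named genes of the ventral cord and AWC comparisons and on lin-15A and lin-15B in carriers and other libraries, singled out 5 of 57 groups of values, where chance gives about 1 in 20. Of these, 4 lay in the same library, unc-47 replicate 2, where the log2 ratio of cholinergic over GABAergic motor neurons (with 10 CPM added to each arm) was −3.69 for ttr-39 (−12.27 to −9.81 in the other 6 libraries). For unc-25 it was −3.37 (−13.08 to −9.82 in the others). For unc-30 it was −4.30 (−8.64 to −7.03 in the others). For unc-46 it was −4.14 (−8.69 to −6.79 in the others). The other one was ntc-1 in the ift-20 library, where the log2 ratio of AWC_ON over AWC_OFF was 7.28 (10.15 to 10.39 in the other 3 libraries).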

How the results depend on the processing

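Scaling by total counts alone was chosen only after the results had been seen; the other alternatives were planned. Counted by named gene and alternative, direction and side of the threshold were kept in 1447 of 1447 values over 58 results for neurons against non-neuronal cells, 978 of 987 for ciliated neurons, 667 of 680 for pharyngeal neurons, 421 of 422 for the ventral cord, 216 of 246 for ASE and 231 of 262 for AWC. Apart from the fixed marker genes, named genes were chosen for their calls, directions, fold changes or p in these same libraries. High retention was thus largely set by the choice and is no separate evidence. Alternatives in which a gene had no value were not counted. Without the ift-20 library all 24 named ASE genes with a value lost their call, with direction kept. In the 2 remaining libraries the log2 ratios were −8.39 and −8.80 for gcy-14, and −5.62 and −6.32 for lim-6. The direction of eat-4, which was not called, turned in ciliated neurons with version 2 libraries alone (0.14). In pharyngeal neurons it turned without the filter on low counts (−0.12), with a minimum of 100 cells (−0.17), with version 3 libraries alone (−0.031), with cells of at least 500 UMIs (−0.27), and without the tph-1 and ceh-10 (−0.09), ceh-34 (−0.23) or unc-53 (−0.06) library; without the nlp-13 and ceh-2 library it was 0.49. The cause was not tested.

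Counts of called genes varied with the settings. Without the filter on low counts, where more genes were tested, edgeR called 14217 genes for neurons, 7111 for ciliated neurons, 3847 for pharyngeal neurons, 731 for the cord, 142 for ASE and 166 for AWC. The Wald test of DESeq2, also run without that filter, called 12155, 5652 and 623 for neurons, ciliated neurons and the cord. These are more than in the main fit but fewer than edgeR called without the filter, and the cause of the difference was not tested. With at most 20 cells per library and type, which leaves fewer UMIs, the counts were 4313 for neurons, 1932 for ciliated and 929 for pharyngeal neurons. With version 3 libraries alone, which are fewer, they were 1096 for ciliated neurons, 684 for pharyngeal neurons and 106 for the cord. A minimum of 100 cells, which leaves only the 2 pan-neuronal of 7 libraries, gave 543 of 1396 tested genes for the cord; the cause was not tested. A minimum of 20 cells gave 136 for ASE, since it leaves out pan-neuronal replicate 2, and 34 for AWC, since it leaves out pan-neuronal replicate 1. Without the library block the counts were 37 for ASE and 33 for AWC, and with cells of at least 500 UMIs 30 for AWC.

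Leaving out each library in turn gave 6609 to 7221 genes for neurons, 2806 to 3454 for ciliated neurons, 1292 to 1499 for pharyngeal neurons, 166 to 327 for the cord, 0 to 136 for ASE and 34 to 67 for AWC. The count of 0 came without the ift-20 library (edgeR; 63 higher and 56 lower at an unadjusted p under 0.05), and 136 without pan-neuronal replicate 2. Without AWC's pan-neuronal replicate 1 the count was 34, and without the ift-20 library 36. Of 41 lists called by camera over the 6 comparisons, 1 kept its call with an estimated correlation. Shares of target types with cells of at least 500 UMIs were 41.7% and 23.4% (unc-47 replicates 1 and 2), 89.9% (nmr-1), 84.4% (eat-4), 9.07% (unc-3), 98.7% (ift-20), 86.6% (tph-1 and ceh-10), 78.7% (acr-2), 79.3% (ceh-34) and 87.8% (unc-86); the cause was not tested. Lists beyond the random range in specificity numbered 16 to 19 under the alternatives. Inside it came glutamate receptor genes with version 2 libraries and mitochondrially encoded genes with version 3 libraries. So did synaptic vesicle and dense core vesicle genes with a minimum of 30 cells. With a minimum of 50 CPM, innexin genes came to lie above it and intestine genes below it. No value could be had from version 3 libraries alone for ASE and AWC. The limit of 20 cells per type was not run for them and gave none for the cord, since VD_DD is the 1 GABAergic type there and 20 of its cells are under the minimum of 30. The library block already pairs the 2 arms of each library. By replicate number, no paired analysis was possible because the 6 comparisons lie within libraries and the sets of libraries compared for transgenes hold mostly sorts with 1 library.

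Swapping the arms within randomly chosen libraries gave at most 4627 genes for neurons (7293 with the real arms), 1570 for ciliated neurons (3087), 955 for pharyngeal neurons (1476) and 27 for the cord (245). The real arms were the 1 split of 60 with as many genes in each. The arms come from the annotation, which could rest on expression of the same genes, so mixing them would lower the count anyway. These splits therefore cannot exclude chance. For ASE (70, highest other 0) and AWC (60, highest other 0), the 4 and 8 splits are too few for a share under 0.05. In those other splits edgeR gave 1 to 8 genes for ASE and 2 to 17 for AWC at an unadjusted p under 0.05. In simulated data a fold of 2 was recovered for 13.6% of changed genes in the comparison of neurons and 69.0% in AWC.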

Other observations

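The tests of a mislabelled sample and of the share of coelomocytes were chosen only after the result was seen. Heat shock genes took 0.968% of the UMIs of neuron types in the ift-20 library and 32.6% in the nmr-1 library, with 26.4% and 27.2% in the cho-1 libraries, 1.27% and 9.25% in the unc-47 libraries and 14% and 13% in the pan-neuronal libraries. The authors annotated part of the RIV and SMD neurons as stressed. In cho-1 replicate 1, heat shock genes summed to 437794 CPM in stressed and 314306 CPM in other RIV cells, and to 435174 CPM in stressed and 208440 CPM in other SMD cells. Neuropeptide genes were lower in the stressed cells of that library, at 92521 CPM against 188624 CPM in RIV and 76092 CPM against 152538 CPM in SMD. In unc-47 replicate 2 the order was the opposite for SMD, with heat shock genes at 44037 CPM in 10 stressed and 96511 CPM in 21 other cells. These values had no test.

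The level of heat shock genes might follow the length of the SDS-DTT treatment. Over 17 libraries Pearson's r with the minutes of treatment was −0.00924 (permutation p = 0.971, two-sided) and Spearman's rho −0.0416 (permutation p = 0.874), 1 relation in its family. Within version 2 libraries r was −0.286 (n = 11) and within version 3 libraries 0.330 (n = 6), with permutation p = 0.391 and 0.666. Without the 2 unc-47 libraries, taken by order from those tied at 4 minutes, r was 0.197. The rise set in advance for this explanation, a positive r with p under 0.05, was not seen. At 2 minutes with version 2, the level adjusted for neuron type ran from −2.46 (ift-20) to 1.41 (nmr-1), so the length of treatment was not the whole source of the spread. With minutes of 2, 3 or 4 only, a weaker relation stays undecided.

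Coelomocytes, scavenger cells of the body cavity, made up 28.8% of the cells of the eat-4 library, 9.22% of the library labelled unc-3 and 1.35% of the ceh-34 library, and 0.0787% to 0.496% of the other 14. These 3 are the libraries whose strain labels name mCherry (two-sided exact permutation p = 0.00147, the smallest of 680 regroupings). The sort for red fluorescence may have taken up coelomocytes in these strains, a hypothesis drawn from the same data.

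unc-54, a myosin gene of body wall muscle whose 3' end is common in reporter plasmids, took 0.000597% (eat-4) to 40.7% (ift-20) of the UMIs of neurons, with a median of 5.91% over libraries, and was higher in neurons than in the non-neuronal cells other than muscle in 16 of 17. Free RNA from muscle cells would keep unc-54 in the ratio to other muscle genes that muscle cells have, but in the median library the ratio was 1298 times higher in neurons, and it was more than 3 times higher in 14 of 15 libraries with at least 10 muscle cells, eat-4 being the exception (0.220). This argues against free muscle RNA, although unc-54 was at only 451 to 10224 CPM in muscle cells, where the other muscle genes summed to 179768 to 298719 CPM: whether the gene models undercount unc-54 was not stated, and free muscle RNA would be undercounted alike. Reporter transcripts that end in unc-54 sequence may be the source. Target types held more unc-54 than other neurons in 7 of 10 sorted libraries (ratios 0.398 to 4.94), between the 9 set in advance for this explanation and the 5 set against it. The other neurons passed the same sort and may hold the reporter too, so this contrast cannot decide. In the eat-4 library it rested on 33 UMIs of unc-54. The explanation stays open, since without reads these transcripts cannot be told apart from those of unc-54, and no biological explanation was tested.

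cho-1 averaged 53368 CPM in the cho-1 libraries and 416 CPM in the others in 4 types with unc-17 at 500 CPM or more in the other libraries (AS, DA, DB and SAB). In 40 types below that minimum it averaged 22215 CPM against 246 CPM. This minimum does not separate cholinergic from other types. VA, VB, VB01 and VB02, counted above as cholinergic cord motor neurons, are among the 40, with unc-17 at 230 CPM in VB01 in the other libraries. How many of the remaining types are cholinergic was not assessed, so the average of the 40 is not that of non-cholinergic cells. Free RNA from the sorted cells would add little to cells that hold the transcript themselves. A median log2 difference of 7.13 in the 4 types with high unc-17 (6.76 to 10.66) therefore argues against it as the whole source there. unc-17 differed by 0.14 in these types, and a general gain of cholinergic transcripts would have raised it. Transcripts of the gene copies on the transgene may be the source in these types, a hypothesis found and tested on the same 2 libraries. No biological explanation was tested, since the cho-1 libraries are the only ones of their strain.

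In the library labelled unc-3, the types listed for unc-3 made up 8.53% of neurons, rank 6 of 17 libraries. A wrong label would leave pha-1, which this strain carries, at the level of strains without it. Its deviation was instead 1.81 above the highest of them (43 CPM, against at most 4.16 CPM). In the other carrier, the ift-20 library, 96.9% of neurons were of its own target types. These values argue against a mislabelled sample. A reporter active in other neurons may account for their capture: unc-54 in the other neurons was 21.6% of its level in the target types (111713 CPM against 517200 CPM, with 6864 CPM in non-neuronal cells other than muscle), between the 10% set in advance against this explanation and the 50% set for it. It stays open, and with 1 library no biological explanation was tested.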
